A study of Mus musculus with 8 samples.

How the data were processed

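Biotin-labelled total RNA from sorted germinal centre B cells of mouse spleen was hybridised to the Illumina mouse WG-6 v2.0 beadchip, per the labels, with 8 deposited samples in 2 groups of 4, MYC wild type and MYC V394D. The groups and replicate numbers were taken from the sample titles and genotype labels. The authors deposited a table of non-normalized probe brightness, in which each value is an intensity on a linear scale. Per the file headers it names the samples but holds neither detection p-values nor labelled control probes. The authors also deposited bead files that give the intensity of each bead, with its bead code and place on the strip. A table of processed values on a log2 scale was deposited by the authors as well. Per the submitters' processing notes, lumi was used; its version, transformation and settings are not given in the sources used here. The processed values correlated at 0.989 with the log2 of the deposited intensity over probes and arrays, with a slope of 0.974 over bright probes. Their medians were nearly equal in all columns, at 7.17. Direction and a log2-like scale were thus settled from the data, while the transformation at low brightness stays unknown. All per-sample columns were used.

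Bead files were summarised with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Each strip held 999286 to 1052605 beads, with a median of 21 or 22 beads for each of 46547 bead codes. Averaging the beads of a code after leaving out those over 3 median absolute deviations from the code's median gave the probe table's values within 0.0001 for at least 99.9978% of the matched probes in each sample, and 99.98% of probes were matched. The file names place the samples at 4 positions of 1 chip, 2 strips each, and this was checked against the bead noise. Over 11201 codes, the mean squared difference between strips in units of bead noise was 1.47 to 1.57 for the 4 pairs of strips of 1 position, 4.67 to 5.58 for the 8 other pairs within a group and 6.87 to 11.64 for the 16 pairs between groups. The SD of the log2 difference was 0.147 to 0.159, 0.254 to 0.284 and 0.307 to 0.405. Strips of 1 position thus differed by slightly more than bead noise and far less than any other pair. They were averaged after normalization, and each counts with its partner as 1 array, so n is 2 arrays in each group. The design written before the data were examined took the 8 samples as separate. That fit is given as an alternative.

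Of 46237 probes, 35784 were listed with 1 gene symbol, 0 with several and 10453 with none. Symbols were brought up to date through entrez numbers (28620 probes), accessions (2637), current symbols (2128) and unique synonyms (2343) of the GRCm38.p6 gene table, and 56 were kept as given. That table served only for names and for which genes neighbour each other.

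The planned background correction from control probes or detection p-values could not be run on this table, so its written fallback was used: limma 3.58.1 in R 4.3.3, normexp background correction with an offset of 50, quantile normalization between strips, and the brighter 50% of probes by mean log2 intensity (23119 probes). A gene was represented by its brightest retained probe, which left 11953 genes. They were tested with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 2 residual degrees of freedom per gene, to which the prior added 6.12, and the median SE of a log2 fold was 0.117. Folds are V394D over wild-type MYC.

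Gene lists were fixed before the data were examined, 47 in all, from general knowledge of germinal centre B cells, MYC, Miz1 and other cells of the spleen. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 47 lists, each with at least 3 measured genes. Camera with an estimated correlation, camera on ranks and limma's fry were alternatives. The named genes follow a rule fixed in advance: the 12 with the largest rise and the 12 with the largest fall among called genes whose 4 V394D strips all lay on one side of all 4 wild-type strips, provisional names left out (4 higher and 1 lower called gene), up to 4 members of smallest p from each list, and Myc, Zbtb17, Cdkn1a, Cdkn2b and Cdkn1c always. Kdm6a and the other genes escaping X inactivation were named after their values were seen, as were the genes named for their place beside other called genes.

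The fit was tested on simulated data for this comparison, with 2 arrays in each group, 11953 genes, 200 changed genes and 20 runs. It recovered 21.5% of genes changed by 0.5 log2 units, 95.0% at 1 and 100% at 2 or 3, and 4.83% of calls were false. Genes were simulated as independent, with variances drawn from the prior of this same fit. A false share near the threshold was therefore built in and does not measure the real rate. In the same simulation, camera with the preset correlation called 59 of 60 lists shifted by 0.2 log2 units and 0.126% of unshifted lists, fry called 5 of the 60, and camera with an estimated correlation called 0. These rates hold for independent genes and do not carry over to lists of correlated genes.

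Alternatives were no background correction, an offset of 16, median scaling, cyclic loess, the authors' log2 values, no filter, the brightest 25% of probes, the mean of a gene's probes, array weights, a trended and robust prior, the replicate number as a block, chip position as a random block, other thresholds, probes in place of genes, and leaving out each strip and each array. Positions each held 1 group, and all arrays were on 1 chip, so chip could not be a block. Figures were drawn with matplotlib 3.10.9.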

Results

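Total RNA of germinal centre B cells, sorted directly from mouse spleen, was measured on an Illumina whole-genome bead array. Germinal centres are the sites in lymphoid organs where activated B cells divide, mutate their antibody genes and are selected. Per the labels, all mice were C57BL/6, lacked endogenous Myc in germinal centre cells and over-expressed MYC from the Rosa26 locus. The groups differed in the MYC protein supplied, either wild-type MYC or MYC V394D, and the series title describes the mutant cells as lacking the interaction of Myc with its partner Miz1. MYC is a transcription factor that drives cell growth, and Miz1, encoded by Zbtb17, is a DNA-binding protein through which MYC can repress genes. There were 8 deposited samples, 4 in each group, with 999286 to 1052605 beads per sample. They were the strips of 4 arrays of 1 chip, so each group held 2 arrays, and n = 2 stands for arrays throughout. Nothing in the labels says that the arrays came from separate mice, so p-values measure only the spread between these arrays, which may be technical. The small number of arrays limits the precision.

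The comparison asked how the transcriptome of these cells differed when MYC carried V394D. Of 11953 genes tested, 71 rose and 36 fell in MYC V394D cells, and 39 of these 107 genes changed by at least 2-fold (limma, Benjamini-Hochberg adjusted p under 0.05). The values of the groups did not overlap in 48.1% of genes, where chance gives 33.3%, and 1912 genes had an unadjusted p under 0.05. The targeted gene gave little information. The retained Myc probe was dim, at 6.45 ± 0.05 (SD, n = 2) log2 units with wild-type MYC and 6.49 ± 0.05 (SD, n = 2) with V394D (limma adjusted p = 0.889). Whether it covers the transgene is not known, so it checks neither the deletion nor the labels. Zbtb17 was bright in both groups, 0.32 ± 0.15 (SE) log2 units higher with V394D (limma adjusted p = 0.341). The count of changed genes depended on the arrays and on the scaling: it was 32 without the first wild-type array (replicates 1 and 2) and 72 without the other (replicates 3 and 4). It was 656 without the first V394D array (replicates 1 and 2), 120 without the second, and 1522 when the 8 strips were taken as separate samples. With each array's median shifted to a common value, 18 genes rose and 20 fell, and with the authors' own log2 values 18 rose and 17 fell.

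The clearest differences were in transcripts of the sex chromosomes. Xist, the RNA that silences an X chromosome in female cells, fell by 7.21 ± 0.15 (SE) log2 units, from 13.36 ± 0.31 (SD, n = 2) with wild-type MYC to 6.15 ± 0.07 (SD, n = 2) with V394D (limma adjusted p = 2.563e-07). The V394D level lies below the dim Myc probe, so the size is set by the floor described below, at -7.55 with an offset of 16 and -6.25 with the authors' values. The Y-linked translation factor gene Eif2s3y rose by 5.55 ± 0.12 (SE) log2 units, from 5.85 ± 0.17 to 11.41 ± 0.04 (SD, n = 2 each; limma adjusted p = 2.563e-07). A second retained Eif2s3y probe was dim and did not follow, at -0.01 (limma adjusted p = 0.989), and the mean of the gene's probes gave 2.77. The wild-type level of Eif2s3y lies near the floor of 5.64 that the background offset sets, so the size of the rise depends on the offset, at 6.84 with an offset of 16 and 4.42 with the authors' values. Kdm5d, a Y-linked histone demethylase, rose by 1.84 log2 units (limma adjusted p = 6.298e-04), or 2.53 and 1.19 with the same alternatives, and Uty was 0.22 log2 units higher without passing the test (limma adjusted p = 0.354). Kdm6a, an X-linked demethylase that escapes X inactivation, fell by 0.76 ± 0.11 (SE) log2 units (limma adjusted p = 0.0259), a call lost with the authors' values (0.0558), with the mean of its probes (0.0935) and without either wild-type array (0.103 and 0.149). Both wild-type arrays had high Xist and both V394D arrays had high Eif2s3y, so donor sex by these transcripts runs with genotype in every comparison given here.

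Of the 24 genes named by size, 15 had a dimmer group within 0.5 log2 units of the dim Myc probe or below it. All 15 changes were larger with an offset of 16 and smaller with the authors' values. Of the other 9, 9 were larger and 8 smaller, so these directions do not set the dim genes apart. The span between these alternatives did, at 18.0% to 80.2% of the change (median 59.9%) in the 15, against 0.207% to 38.4% (median 17.6%) in the other 9. The sizes of the 15 thus depend strongly on the background treatment, and those of bright genes such as Rpl29, Igkv9-124 and Bcat1 hardly. All are given in log2 units. Among other genes that rose with V394D, Jhy rose by 2.44, its V394D arrays differing widely (SD 0.89 log2 units), with 3.15 at an offset of 16 and 1.72 with the authors' values. Zyx, encoding the focal adhesion protein zyxin, rose by 1.71 (1.81 and 1.56 with these alternatives). Rflna, an actin-organising factor, rose by 1.77 (2.33 and 1.19), and Prg2, the eosinophil granule major basic protein, rose by 1.69 (1.92 and 1.36). Dlgap5, a mitotic spindle protein, rose by 1.52, and Ptpn22, a phosphatase that restrains antigen receptor signalling, rose by 1.25. Nrep (1.26), the antibody light chain segment Igkv9-124 (1.52) and the related genes Speer3 (1.61) and Speer1 (1.27) completed the named set, with limma adjusted p between 6.298e-04 (Zyx, Rflna) and 0.0361 (Igkv9-124). Members of the Speer and antibody segment families are near-identical in sequence, so their probes may not tell members apart. The calls of Igkv9-124, Nrep, Speer1 and Ptpn22 were lost with median scaling and with the authors' values, and that of Jhy with the authors' values. With a trended and robust prior Jhy and Igkv9-124 lost theirs (limma adjusted p 0.244 and 0.135), and Igkv9-124 also with the mean of probes (0.0594). Without the first wild-type array Jhy, Igkv9-124 and Speer1 lost their calls (limma adjusted p 0.0931, 0.144 and 0.0841). Without the other wild-type array Jhy and Nrep did (0.0607 and 0.116).

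Wdr82, Dusp7, Ackr4, Rpl29, Parp3 and Pik3r4, all lower with V394D, lie in the same run of neighbouring called genes, described below. Their falls may therefore not be separate effects. Among genes that fell with V394D, Wdr82, a subunit of a histone H3 methyltransferase complex, fell by 3.11 ± 0.13 (SE) log2 units (limma adjusted p = 3.609e-05). The change was -3.63 with an offset of 16 and -2.46 with the authors' values. Its other retained probes were 0.25 and 0.14 log2 units higher, so the gene's probes disagree, and the mean of all 3 fell by 0.90. Dusp7, a phosphatase acting on MAP kinases, fell by 2.20 log2 units, and Ackr4, a scavenging receptor for the chemokines CCL19 and CCL21, fell by 2.22 (-2.64 and -1.69 with these alternatives), with its other retained probes at -1.24, -0.34 and 0.08 and a mean over all 4 of -0.93. The ribosomal protein gene Rpl29 fell by 1.44 at its brighter probe, and the other probe fell by 4.20. Parp3, an enzyme that acts at DNA breaks, fell by 1.63, and Pik3r4, the regulatory subunit of the VPS34 lipid kinase, fell by 1.59 (-2.19 and -1.02), with other retained probes at -0.39 and -0.38 and a mean over all 3 of -0.78. Gpr176, an orphan receptor, fell by 2.27 (-2.94 and -1.58). Wls, which carries Wnt proteins to the cell surface, fell by 1.90 (-2.37 and -1.36), and Ccnb1ip1 fell by 1.66 (-2.37 and -1.04). Bcat1, which starts the breakdown of branched-chain amino acids, fell by 1.10, and Aif1l fell by 1.06 (-1.41 and -0.70). The limma adjusted p of these genes lay between 3.609e-05 (Wdr82) and 0.0213 (Bcat1). Bcat1 lost its call with median scaling, with the authors' values and without the first wild-type array (limma adjusted p 0.111). Ccnb1ip1 lost it with the authors' values.

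**Figure D1:**
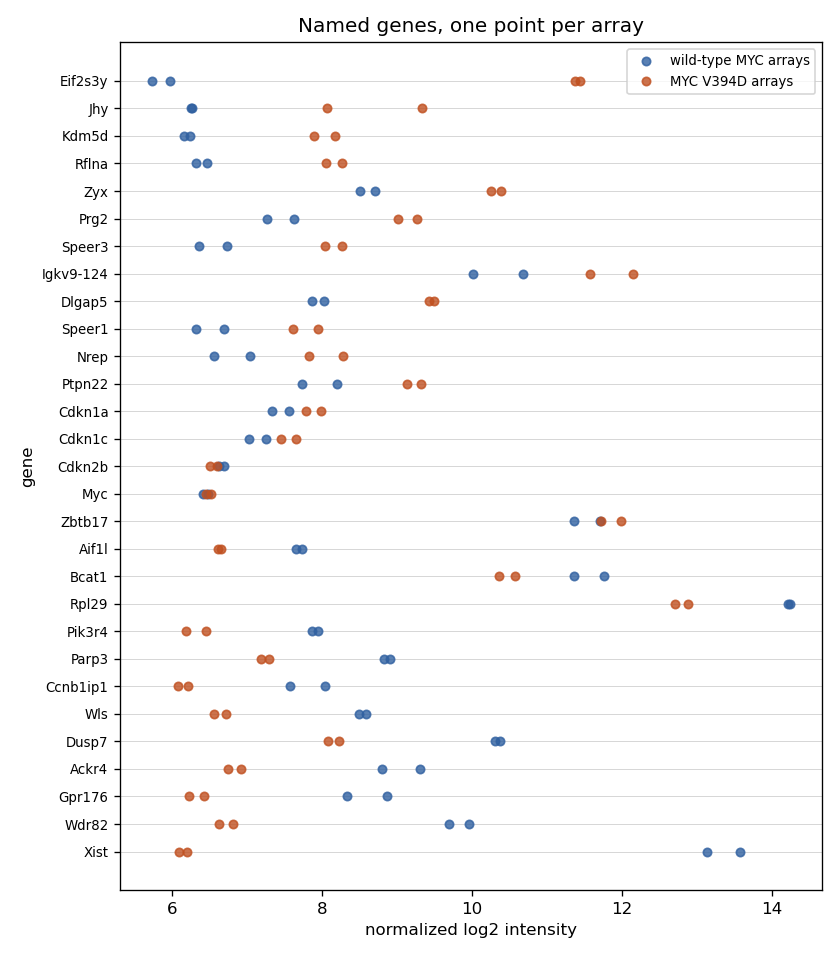
Normalized log2 intensity (x axis) of the named genes (y axis), with 1 point per array, 2 arrays with wild-type MYC and 2 with MYC V394D. Xist and Eif2s3y separate the groups most widely, while the Myc points lie together near 6.45 and 6.49.

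Of the 47 gene lists, 12 were shifted higher and 9 lower in V394D cells by limma's camera test with a preset correlation of 0.01 (Benjamini-Hochberg adjusted p under 0.05). The 12 include the sex-linked genes (camera adjusted p = 0.0334), where a direction has no meaning, since 3 Y-linked members were higher and Xist lower. That call was lost with the authors' values (0.0578), the mean of probes (0.0651), the replicate block (0.0549), camera on ranks (0.185) and without the second wild-type array (0.0617). None of the 21 passed in camera with an estimated correlation, where adjusted p was 0.582 or higher and 0 lists had an unadjusted p under 0.05. The same held in limma's fry, where adjusted p was 0.240 or higher and 8 lists had an unadjusted p under 0.05. In the simulation the estimated correlation called 0 of 60 lists shifted by 0.2 log2 units, and fry called 5. Failing these tests therefore does not decide whether a list was shifted. With the arrays regrouped so that each group held 1 array of each genotype, camera still gave 7 and 4 lists, so some calls of this kind arise without a genotype difference.

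Genes of the light zone and of CD40 and B cell receptor activation, which mark germinal centre cells undergoing selection, were shifted higher in V394D cells. Of 26 measured members, 24 had a positive fold and 3 rose, 8 when adjusted over the list alone, and the median was 0.30 log2 units (camera adjusted p = 3.423e-08; adjusted p = 0.582 with an estimated correlation). Cd69, an early activation antigen, rose by 0.93 ± 0.12 (SE) log2 units, Il4i1, an amino acid oxidase, rose by 0.85 ± 0.12, and Tnfaip3, a brake on NF-kB signalling, rose by 0.73 ± 0.11, with limma adjusted p of 0.0159, 0.0221 and 0.0348. All 3 lost their calls with median scaling, with the authors' values and without the first wild-type array (limma adjusted p 0.120, 0.169 and 0.234). The same held for Il4i1 and Tnfaip3 without the other wild-type array (limma adjusted p 0.0574 and 0.108), for Tnfaip3 with an offset of 16 (0.0517), and for Tnfaip3 without the second V394D array (0.0660). Cd69 also lost its call with the mean of its probes, at 0.51 log2 units (limma adjusted p = 0.0893). Cd40 was 0.51 ± 0.11 log2 units higher (limma adjusted p = 0.0849).

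Antigen presentation on MHC class II showed a shift of the same kind. All 13 measured members had a positive fold with a median of 0.34 log2 units. Of these, 0 passed over all genes (limma; 9 had an unadjusted p under 0.05), 7 when adjusted over the list alone (camera adjusted p = 2.693e-06; adjusted p = 0.582 with an estimated correlation). Ciita, the master regulator of these genes, was 0.49 ± 0.11 (SE) and H2-Ob 0.49 ± 0.11 log2 units higher (limma adjusted p = 0.107 for each). Macrophage and monocyte markers, which a sort could also carry, were shifted higher too (13 of 16 positive, median 0.14; camera adjusted p = 0.0281; adjusted p = 0.675 with an estimated correlation), with Lyz2 at 1.03 ± 0.20 (SE) log2 units (limma adjusted p = 0.0696). Their mean differed by 0.28 between the wild-type arrays and by 0.36 between the V394D arrays, more than the 0.22 between the groups. The list's call was lost without the first wild-type array (camera adjusted p = 0.657), without the second V394D array (0.483) and with the authors' values (0.0633).

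Memory B cell-associated genes were higher in 15 of 18 members, with a median of 0.34 log2 units. Of these, Gpr183, a receptor that guides B cells to the follicle edge, rose by 0.80 ± 0.10 (SE; limma adjusted p = 0.0170), and 9 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.659e-05; adjusted p = 0.582 with an estimated correlation). Zbtb32 went the other way, at -0.74 (limma adjusted p = 0.0673). Genes of naive follicular B cells were positive in 8 of 10 members, with 0 past the test over all genes (limma; 5 at an unadjusted p under 0.05) and 5 over the list alone (camera adjusted p = 0.00849; adjusted p = 0.582 with an estimated correlation). Fcer2a, which encodes CD23, was 0.75 ± 0.14 (SE) log2 units higher (limma adjusted p = 0.0574), and Klf2 0.64 ± 0.17 higher. Plasma cell genes were positive in 16 of 19 members, with a median of 0.25 (camera adjusted p = 1.266e-04, or 0.582 with an estimated correlation). Of these, 0 passed over all genes (limma, with 8 at an unadjusted p under 0.05) and 3 over the list alone. Fkbp11 was at 0.94 ± 0.20 (SE) and Pdia4, an endoplasmic reticulum chaperone, at 0.56 ± 0.11 (limma adjusted p = 0.0798 and 0.0762). Of 3 measured antibody constant region genes, Ighg1 rose by 0.88 ± 0.13 (SE) log2 units (limma adjusted p = 0.0221). Ighm was 0.53 ± 0.13 higher without passing (limma adjusted p = 0.122). Igkc was at -0.04 ± 0.10, or 0.16 with cyclic loess. It is brighter than nearly all probes (percentile 99.998), where quantile normalization gives every array nearly the same value, so this fold says little. The list of these 3 genes was called (camera adjusted p = 0.0223, or 0.582 with an estimated correlation). The list lost its call with camera on ranks (adjusted p = 0.137). Ighg1 lost its call with median scaling and with the authors' values, and Gpr183 with median scaling. Without the first or the second wild-type array the calls of Gpr183 (limma adjusted p 0.134 and 0.0843) and Ighg1 (0.169 and 0.0525) were lost. Without the second, that of the naive list was lost too (camera adjusted p = 0.0515).

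Several lists of biosynthesis and energy metabolism were shifted lower in V394D cells, each by little. Glycolysis was not called, with 12 of 17 members negative and a median of -0.09 (camera adjusted p = 0.329). There Eno1b was at -0.59 and Pkm at -0.67 log2 units (limma adjusted p = 0.0574 and 0.233). Slc2a1, a glucose transporter, was 0.30 log2 units higher (limma adjusted p = 0.263). Over the list alone 1 member fell and 0 rose. In ribosome biogenesis, 36 of 37 members had a negative fold with a median of -0.19 log2 units. Of these, 0 passed over all genes or over the list alone (limma; 12 were lower at an unadjusted p under 0.05; camera adjusted p = 1.921e-06; adjusted p = 0.582 with an estimated correlation). Rrp9, which acts in processing ribosomal RNA, was at -0.41 ± 0.11 (SE), and Polr1e, a subunit of RNA polymerase I, at -0.39 ± 0.12. Genes that MYC is known to activate were lower in 33 of 36 members, with a median of -0.20. Of these, 0 passed over all genes (limma; 12 lower and 1 higher at an unadjusted p under 0.05), against 5 lower and 1 higher over the list alone (camera adjusted p = 5.577e-06; adjusted p = 0.584 with an estimated correlation). Nolc1, a nucleolar protein, was at -0.46 ± 0.10 (SE), while Ccnd2, encoding cyclin D2, was at 0.73 ± 0.15 (limma adjusted p = 0.0995 and 0.0735). The V394D level of Nolc1, 6.89, lies close to the dim Myc probe, so its size may depend on the background offset. Oxidative phosphorylation genes were lower in 36 of 38 members (median -0.19; camera adjusted p = 1.341e-05; adjusted p = 0.582 with an estimated correlation), with 0 past the test over all genes (limma; 5 at an unadjusted p under 0.05). Cycs, encoding cytochrome c, was at -0.57 ± 0.15 (SE).

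Enzymes of serine, one-carbon and nucleotide synthesis were lower in 22 of 25 members, with a median of -0.23 log2 units, and 8 fell when adjusted over the list alone (camera adjusted p = 1.386e-05; adjusted p = 0.584 with an estimated correlation). Dctpp1, which degrades dCTP, fell by 0.68 ± 0.11 (SE; limma adjusted p = 0.0361). This call was lost with an offset of 16, with median scaling and with the authors' values. It was lost too without either wild-type array, where the fold stayed at -0.68, and without the second V394D array, where it was -0.61. Phgdh, the first enzyme of serine synthesis, was at -0.46 ± 0.11 without passing (limma adjusted p = 0.110). Heat shock genes were negative in 12 of 13 members (camera adjusted p = 0.00447; adjusted p = 0.584 with an estimated correlation). Among them, Hsp90aa1 fell by 0.66 ± 0.12 (SE) at the edge of the threshold (limma adjusted p = 0.0492). It lost the call with no background correction, an offset of 16, the authors' values, cyclic loess, median scaling, the brightest 25% of probes or the mean of probes, and without either wild-type array (limma adjusted p 0.305 and 0.128) or the second V394D array (0.0952). Translation factors and tRNA synthetases (28 of 33 negative; camera adjusted p = 0.00150), genes of the G1/S transition and DNA replication (29 of 37 negative; camera adjusted p = 0.00577), cholesterol and fatty acid synthesis (17 of 20 negative; camera adjusted p = 0.00849) and mitochondrial biogenesis (19 of 25 negative; camera adjusted p = 0.0153) were shifted lower as well. Their adjusted p was 0.582 or 0.584 with an estimated correlation. Without the second V394D array (replicates 3 and 4), the calls of the last 4 lists were lost (camera adjusted p 0.159, 0.433, 0.110 and 0.0845). That of cholesterol and fatty acid synthesis was lost also without the first wild-type array (0.0713).

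**Figure D2:**
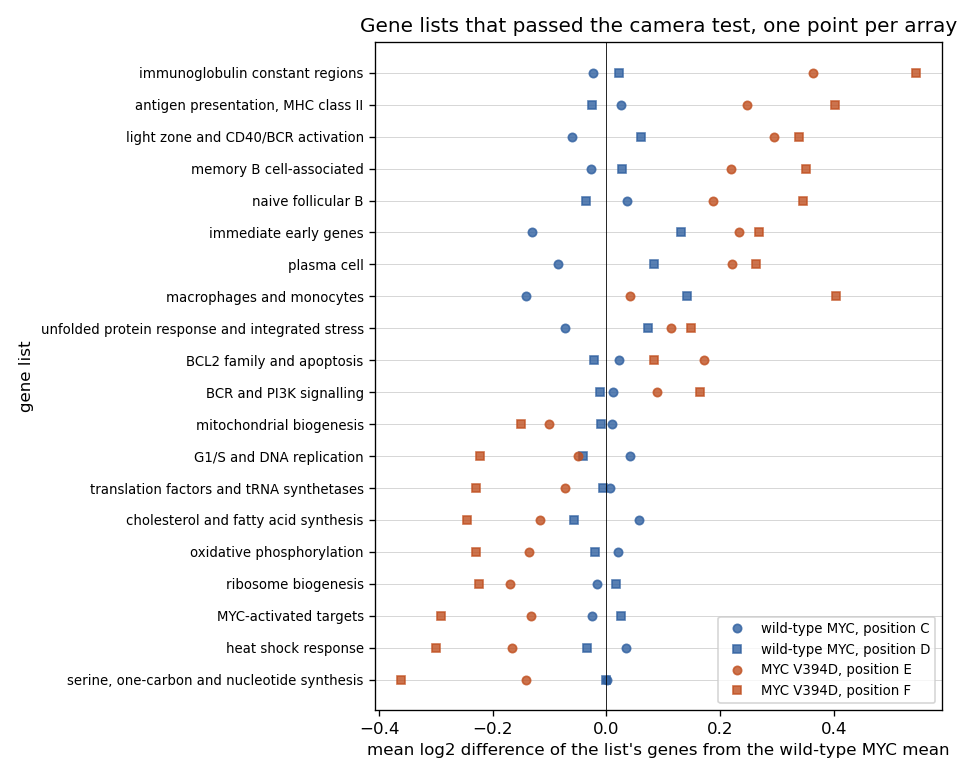
Mean log2 difference from the wild-type MYC mean (x axis) for the genes of each list that passed the camera test (y axis), with 1 point per array and the sex-linked list left out. For ribosome biogenesis the V394D arrays lie at -0.17 and -0.22 and the wild-type arrays at -0.02 and 0.02; for MHC class II the V394D arrays lie at 0.25 and 0.40.

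Genes reported to be repressed by MYC through Miz1 were the group most closely tied to the question of the series. Of 12 measured, 9 had a positive fold with a median of 0.11 log2 units. Of these, 0 passed over all genes (limma, with 4 higher at an unadjusted p under 0.05), and 4 passed when adjusted over the list alone. The list as a whole was not called (camera adjusted p = 0.0834). Cd9, a tetraspanin, was 0.44 ± 0.12 (SE) log2 units higher and Bcl2, the anti-apoptotic protein, 0.42 ± 0.11 higher (limma adjusted p = 0.135 and 0.147). The wild-type level of Cd9, 6.56, lies close to the dim Myc probe, so its size may depend on the background offset. The cell cycle inhibitor Cdkn1a (p21) was 0.45 ± 0.13 higher (limma adjusted p = 0.165), with its other probes at -0.11 and 0.07. Cdkn1c (p57) was 0.42 ± 0.13 higher (limma adjusted p = 0.184) and Cdkn2b (p15) was at -0.11 ± 0.11 (limma adjusted p = 0.671). With no filter on dim probes the list passed (camera adjusted p = 0.0451); with the filter its adjusted p = 0.582 with an estimated correlation. In the list of cyclin-dependent kinase inhibitors, 3 of 8 were higher and 1 lower over the list alone (camera adjusted p = 0.318). Among them, Cdkn1b (p27) was 0.53 ± 0.11 (SE) higher (limma adjusted p = 0.0760). Its wild-type level of 6.23 lies below the dim Myc probe, so the size depends on the background offset. With an offset of 16 it was 0.86 (limma adjusted p = 0.0359).

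Genes of germinal centre identity were not shifted as a list (8 positive and 12 negative of 20, median -0.07; camera adjusted p = 0.329), nor were those of the dark zone, where germinal centre cells divide (2 positive and 7 negative of 9, median -0.18; camera adjusted p = 0.167). The dark zone list passed without the second wild-type array (camera adjusted p = 0.00179) or the first V394D array (0.0405) and turned direction without the first wild-type array (0.967). Mitosis genes were negative in 24 of 34 members (median -0.07; camera adjusted p = 0.202) with Dlgap5 the 1 member that rose, and the list passed without the first V394D array (0.0374) and turned direction without the second (0.900). Cytosolic ribosomal protein genes had a median of -0.03 (camera adjusted p = 0.140), and Rpl29 was the 1 of 49 that fell. This list passed with median scaling (camera adjusted p = 0.00678), no filter (0.0404) or the mean of probes (0.0300).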

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

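The tests of other called genes by sex, of neighbouring genes, of other probes, of the steps along the chip and of the splits were chosen after the results were seen. Probes with no listed gene symbol were outside the gene comparison, and 37 of 4217 retained ones passed a limma adjusted p of 0.05, 29 higher and 8 lower with V394D; their genes are not named here.

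Sex-linked transcripts separated the groups. If the donors differed in sex, genes that escape X inactivation should be lower with V394D, and the median of 5 measured ones was -0.62 log2 units. Of these only Kdm6a passed (-0.76; limma adjusted p = 0.0259), Eif2s3x (-0.73; 0.114), Pbdc1 (-0.62; 0.138) and Ddx3x (-0.27; 0.278) were lower without passing, and Kdm5c was near 0 (-0.06; 0.933). The median is in line with female donors for the wild-type arrays and male donors for the V394D arrays. How much of the 103 called genes outside the sex-linked and escape genes comes from donor sex cannot be told apart from genotype, since no group holds both sexes. The effect of V394D itself stays open for each of them, as untested.

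Called genes neighboured each other in gene order. Of 107 called genes, 39 had another called gene within 10 tested genes, where 10000 random draws gave a median of 17, a 95th percentile of 26 and a highest count of 37 (permutation p = 1e-04, the smallest these draws can give). Without antibody segments, Speer and zinc finger families and the sex chromosomes it was 25 against a median of 12 (permutation p = 0.0058). The longest run held 11 called genes within 35 tested, 8 lower (among them Wdr82, Dusp7, Ackr4, Parp3, Pik3r4 and Rpl29) and 3 higher (Cish, Hemk1 and Cpne4, calls lost with median scaling and with the authors' values). A linked interval that differs between the breeding lines may be its source, as a hypothesis. Sequence differences under single probes stay open. Over all 13 runs, 11 neighbouring genes had another comparable probe. In the longest run, Ackr4 had such a probe that moved the same way by at least 50% of the change (-1.24). Those of Pik3r4 (-0.39, -0.38 and -0.10) and Cpne4 (0.004) did not. Over the 11 genes, 6 had at least 1 such probe that did, with an exact 95% interval of 23.4% to 83.3%. In 5 of 11 most such probes did (16.7% to 76.6%), so the bound of more than 50% set for excluding them is passed only by the first count. Both intervals reach the 25% that would fit them, a condition added after the first count was seen. Over all called genes, a wider set than the pattern, the first count was 20 of 35 (39.4% to 73.7%), which clears that limit but does not settle the neighbours. Retained probes much dimmer than the chosen one were outside these counts and went both ways in the longest run. They were at 0.25 and 0.14 for Wdr82, -0.34 and 0.08 for Ackr4, and -4.20 for Rpl29.

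The list shifts ran along the chip, since wild-type arrays lay at positions C and D and V394D arrays at E and F, with mean intensity falling from 771 over 673 and 630 to 547. If a linear trend were the whole cause, the step between arrays of a group would be 0.5 of the group difference. It had the same sign as the group difference in 19 of 20 lists with a median ratio of 0.35, but the wild-type step alone did so in 14, against 19 for the V394D step. The mean step was under 0.25 of it, with the upper end of a bootstrap interval under 0.5, in 5 lists. In 11 lists the interval held 0.5. Ratios ran from -0.51 for apoptosis genes to 1.45 for macrophage and monocyte markers. The interval is over genes and leaves out the spread between arrays, so trend and genotype cannot be told apart with 1 step in each group. Against brightness left by quantile normalization, 17 of 21 lists kept call and direction under median scaling, cyclic loess and the authors' values, although each of these treats array-wide differences as technical.

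For the number of called genes, the 4 arrays allow 3 splits into 2 and 2, too few for a share under 0.05. The real split gave 107 genes and 1 of the 3 splits reached that number. The highest other gave 1 gene, and limma found 362 and 76 genes at an unadjusted p under 0.05 in the others. Those splits put 1 array of each genotype in each group. The genotype difference then widens the spread within groups, so their low counts are no measure of chance.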

How the results depend on the processing

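The offset of 16, the brightest 25% of probes and the fits without a whole array were chosen after seeing the data. The fit of 8 separate strips was the planned design, turned into an alternative after the strips were seen, and chip position as a random block was planned; the replicate block on 8 strips was listed as an alternative only after that. All 107 called genes kept their sign in every alternative that measured them (75 measured in the brightest 25%). Much of this was fixed beforehand. In all 107 the 4 strips of each group did not overlap with those of the other group. Leaving out a strip or an array could then turn a sign only through another choice of probe. A call lost without an array need not mean a smaller fold, since fewer arrays measure the spread less well. Array weights, the trended prior, the blocks and the 8 separate strips left the folds as they were. Over all alternatives, the 71 genes followed, those named in the text, kept direction and side of the threshold 1579 times, lost the call 111 times, gained it 130 times and turned direction 3 times. The 47 lists did so 1118, 79, 29 and 36 times, and no list turned that was called before or after. Igkc was at 0.16 with cyclic loess, and without an array Kdm5c ranged from -0.39 to 0.27 log2 units. With median scaling, lists of T cells (camera adjusted p = 0.765), NK cells (0.951), neutrophils (0.675), stromal cells (0.802) and chromatin regulators (0.604) turned. With no filter, stromal (0.756) and endothelial cells (0.914) did, with the brightest 25% T cells (0.471) and mTORC1 (0.977), with the mean of probes chromatin regulators (0.609), and with the replicate block NK cells (0.902, and 0.894 on 8 strips). Without a strip or an array 11 lists turned in at least 1 setting. Their lowest and highest camera adjusted p over all such settings were 0.0374 and 0.900 for mitosis, 0.00179 and 0.967 for the dark zone, 1.988e-06 and 0.901 for interferon, and 0.498 and 0.989 for T cells. They were 0.294 and 0.967 for NK cells, 0.344 and 0.967 for macrophage receptors, 0.0268 and 0.805 for neutrophils, and 0.357 and 0.996 for dendritic cells. Erythroid cells gave 1.818e-05 and 0.808, stromal cells 0.524 and 0.993, and chromatin regulators 0.614 and 0.989. The main counts were 71 higher and 36 lower genes. They were 18 and 20 with median scaling, 18 and 17 with the authors' values, 39 and 23 with the brightest 25% (fewer genes tested), 136 and 59 with a trended and robust prior, 440 and 273 with chip position as a random block, 833 and 689 with 8 separate strips, 179 and 92 at an adjusted p under 0.1, 16 and 12 under 0.01, and 999 and 913 at an unadjusted p under 0.05; apart from the changed thresholds and the number of samples or genes, the cause was not tested. With the replicate number as a block they were 252 and 130 over arrays and 999 and 884 over 8 strips, and the list counts stayed at 12 and 9 over arrays. Calls were exchanged, as interferon (camera adjusted p = 0.0254) and marginal zone genes (0.0379) gained them and apoptosis and sex-linked genes (0.0549 each) lost them; same-numbered arrays deviated together at a correlation of 0.158 over genes with only 2 pairs, and nothing says the numbers are shared. Leaving out a strip or an array gave 15 to 433 higher and 16 to 223 lower genes, 9 to 13 higher and 6 to 12 lower lists; a lone array is assumed to vary like the other group. Lists higher and lower were 12 and 9, against 15 and 11 with no filter, 9 and 9 with camera on ranks, and 0 and 0 with an estimated correlation and with fry. Not run were neqc and the filters on detection p, which the table lacks, and list tests for the trended prior and the random block. Without control probes, how far a dim probe lies above background is unknown.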

Other observations

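Among immediate early genes, Egr2 was at 0.37 and Jun at 0.34 log2 units (limma adjusted p = 0.166 and 0.188). The wild-type level of Jun, 6.71, lies close to the dim Myc probe, so its size may depend on the background offset. The list was positive in 11 of 13 members, with a median of 0.28 (camera adjusted p = 0.00195, or 0.582 with an estimated correlation). The call was lost without the first wild-type array (camera adjusted p = 0.131). Genes of the unfolded protein response and integrated stress were positive in 18 of 23 (camera adjusted p = 0.0136; adjusted p = 0.584 with an estimated correlation), where Asns, asparagine synthetase, went the other way at -0.64 (limma adjusted p = 0.0829). The call was lost without the first wild-type array (camera adjusted p = 0.343). B cell receptor and PI3K signalling genes were positive in 15 of 21 (camera adjusted p = 0.0248; adjusted p = 0.582 with an estimated correlation), a call lost with median scaling (camera adjusted p = 0.377), without the second wild-type array (0.0771) and without the second V394D array (0.110). Apoptosis genes of the BCL2 family and others were positive in 16 of 21 (camera adjusted p = 0.0457; adjusted p = 0.582 with an estimated correlation), with Birc2 at 0.53 and Bmf, a pro-apoptotic member, at -0.51 (limma adjusted p = 0.0726 and 0.0841). The list lost the call in most alternatives, with camera adjusted p of 0.110 under median scaling and 0.0549 with the replicate number as a block.

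Apart from macrophages and monocytes, markers of cells outside the B lineage were not called. Lists of naive follicular B cells, memory B cells and plasma cells were called, as given above. Whether the sort carried such cells was not tested. T cells (median -0.06, camera adjusted p = 0.808) and neutrophils (-0.09, 0.773) turned direction with median scaling. Also not called were erythroid cells (-0.18, 0.140), platelets (-0.18, 0.139), dendritic cells (0.03, 0.784) and endothelial cells (-0.07, 0.639, turned with no filter). Without 1 array or the filter some of these passed, such as erythroid cells without the first wild-type array (camera adjusted p = 1.818e-05). Neutrophil markers differed between arrays of a group instead, at -0.33 and 0.33 for wild-type MYC and -0.38 and 0.27 for V394D. Interferon response genes did likewise, at -0.19 and 0.19 against -0.11 and 0.40 (camera adjusted p = 0.0644; 0.00681 with median scaling, 0.0254 with the replicate number as a block), and turned direction without the first wild-type array (0.901).

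Genes of marginal zone B and B1 cells were not called (6 of 8 positive, median 0.20; camera adjusted p = 0.0811; adjusted p = 0.582 with an estimated correlation). They passed with median scaling (camera adjusted p = 0.0299), no filter (0.0180), an offset of 16 (0.0453) and the replicate number as a block (0.0379). The remaining 11 lists were not called, with camera adjusted p from 0.139 for p53 targets to 0.792 for follicular dendritic and stromal cells. They were also those of the MYC network, cyclins D and kinases, autophagy, mTORC1, somatic hypermutation, NK cells, tingible-body macrophage receptors, histones and chromatin regulators. The p53 list passed with the brightest 25% of probes (0.0471).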
